A study of Mus musculus with 2 samples.

How the data were processed

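DNase I hypersensitivity was measured in 2 mouse samples from C57/Bl6 animals, 1 of bone marrow-derived macrophages and 1 of splenic B cells sorted for CD19 and IgM. DNase I cuts DNA where it is not wrapped tightly in nucleosomes, so that sites of frequent cutting mark promoters, enhancers and other regulatory elements. Per the labels' protocols, nuclease-treated DNA was separated on an agarose gel, fragments of 100 to 600 bp were cut out, and Illumina libraries were made from them. Each cell type had 1 library and no replicate, so no p-value between the cell types was calculated and every difference below is one between these 2 libraries.

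The authors deposited 1 peak list per library. Per the file headers, each list gives for every region a number, the chromosome, the start and end, the position of its maximum and its height. Positions are on the mouse build mm9, per the submitters' processing notes, and are printed as deposited; whether they count from 0 or 1 is not given in the sources used here. The height was taken as the signal at the maximum of the region, a reading the headers do not spell out. The deposited values are never negative and mostly not whole, which does not tell a scaled pile-up of reads from another score. The aligner, the peak caller, its threshold, any extension of the reads and any control library are not given in the sources used here. The heights were not known to be scaled to a common depth, so heights were ranked within a list, with 2 exceptions that applied the same height to both lists, namely the alternative with a common floor on each chromosome and the listing of regions higher than 500. The number of reads behind each list is unknown, because neither list gives it.

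From these files the following was computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1; figures were drawn with Matplotlib 3.10.9. A region was called shared when it overlapped a region of the other list by at least 1 bp, and library-only otherwise. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only and take regions as independent, which neighbouring regions are not. The overlap to be had by chance was taken from 100 random placements of each list on the same chromosomes, between the first and last region of either list, and from moving each list by 10 kb in both directions. Many regions of a list touched the next one end to start. They were counted as deposited, and, where the text speaks of sites, touching regions of a list were first merged into 1 site with the height of its tallest part. The overlap and merging steps were tested on simulated lists built from the 34154 macrophage sites, in which 100% of the planted overlaps were recovered and 0% of the other sites were called shared. Overlaps were planted only where they did not reach the next site. The test thus checks the code, not how the 1 bp rule behaves among dense regions.

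The lowest height in a list was compared between chromosomes. A chromosome whose lowest height exceeded 1.5 times the lowest of the whole list was said to have a raised floor. This was true of chromosome 11 in the macrophage list and of chromosomes 7, 12, 14 and 19 in the B cell list. Results are therefore given for all chromosomes and for the 15 chromosomes with no raised floor in either list; the second set was chosen after seeing the data.

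The comparisons, the overlap rule, the shuffles, most alternatives and the rule for named items were fixed before the data were examined. The rule named the regions of the Pu.1 locus, the 5 highest regions of each class, and genes of 18 lists by their numbers of library-only regions. It also named, among all protein-coding genes, those with the largest differences between macrophage-only and B cell-only regions in either direction. No mm9 genome or annotation was used here, and the gene table at hand is of GRCm38.p6, whose coordinates were neither printed nor converted. Genes near regions, the ranking of all protein-coding genes and the 18 gene lists were therefore not analysed here. Nor were the location of regions relative to genes and the motif shares planned in the design. The 5 highest regions of each class are named by position.

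The Pu.1 locus was sought by spacing instead. The distances of its published upstream elements from the promoter, about -18, -15, -14, -12, -10, -9 and -8 kb, had been written down from general knowledge before the data were examined. The gene table places Spi1 (Sfpi1), the gene of PU.1, on chromosome 2. Regions of both lists were merged, every merged site holding regions of both lists was tried as the promoter in both orientations, and the number of the 7 distances with the maximum of a merged site within 500 bp was counted, without regard to which list the region came from. Regions from 50 kb upstream to 10 kb downstream of the best placement were then listed. The whole search was added after seeing the data. The design had set 1 kb only for matching regions to the published distances from an annotated promoter, and set no tolerance for a search. The tolerance of 500 bp was chosen after seeing the data, and the interval had been inspected, from general knowledge of the gene's position, before the search was run. The end of the gene was not known, so the window ended 10 kb beyond the promoter placement rather than beyond the gene.

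The alternatives were a reciprocal overlap of 50%, a gap of up to 500 bp, 200 bp centred on the maximum, the top 50% of each list by height, lists of equal length, the 10000 highest regions, autosomes only and a wider window around the interval. Added after seeing the data were the 15 chromosomes, a common floor on each chromosome, merged sites, and the spacing search with all 3 of its tolerances, 500, 1000 and 300 bp.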

Results

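The data comprised 2 lists of DNase I hypersensitive regions, made to study regulatory elements of PU.1, the ETS-family transcription factor needed for macrophage and B cell development. The macrophages had been grown from bone marrow for 8 days with L-cell conditioned medium as a source of CSF-1 and with IL-3 conditioned medium, and the adherent cells were taken. The B cells came straight from the spleen. The macrophage list held 58628 regions covering 11.3 Mb, and the B cell list held 72959 regions covering 13.4 Mb. Regions were short, with a median width of 190 bp in macrophages (interquartile range 139 to 242) and 179 bp in B cells (118 to 238). The median height was 9.88 in macrophages (interquartile range 7.23 to 16.0) and 9.25 in B cells (6.21 to 17.96). Both lists covered the 19 autosomes and the X chromosome, and neither held a region on the Y chromosome. Merging of touching regions left 34154 macrophage sites and 37398 B cell sites, of which 39.3% and 46.5% consisted of several deposited regions.

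The first comparison asked how much of the hypersensitive landscape macrophages and B cells had in common. A large part of each list was found in both cell types. Of the macrophage regions, 35855 (61.2%, 95% interval 60.8 to 61.6) overlapped a B cell region, and 22773 were found in macrophages only. Of the B cell regions, 36592 (50.2%, interval 49.8 to 50.5) overlapped a macrophage region, and 36367 were found in B cells only. The numbers of shared regions were thus close, while the B cell list was longer. In lists of equal length the shares were 58.9% and 56.6%, and among the 10000 highest regions of each list 73.4% and 70.9%. Both settings kept the chromosomes with a raised floor, where 1 list lacked low regions. Their closer shares alone therefore do not show how much of the difference comes from list length. Random placement on the same chromosomes gave overlaps of 0.777% ± 0.039 for macrophage regions and 0.687% ± 0.034 for B cell regions (SD over 100 placements). Moving the lists by 10 kb, which keeps regions in their neighbourhoods, gave 3.36% and 2.92%. With regions within 500 bp also counted as shared, the B cell share was the higher one, at 68.5% of macrophage and 69.6% of B cell regions, and a reciprocal overlap of 50% lowered the shares to 37.4% and 30.1%. On the 15 chromosomes with no raised floor, the shares were 68.9% of 44384 macrophage regions (interval 68.4 to 69.3) and 50.3% of 62683 B cell regions (49.9 to 50.6). The numbers of shared regions were again close, at 30568 and 31500. With shared numbers this close, the lower B cell share follows from the longer B cell list. It is no separate sign of a difference between the cell types. On these 15 chromosomes the maxima of overlapping sites lay at a median distance of 51 bp, over 14179 pairs of 1 macrophage and 1 B cell site (interquartile range 17 to 147). Overlap itself limits this distance, and no distance to be had by chance was calculated.

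The chromosomes differed sharply in the B cell list. Chromosome 7 held 528 B cell regions against 4544 macrophage regions, chromosome 12 held 1137 against 2335, and chromosome 14 held 549 against 2075. Chromosome 19 held 1 B cell region against 2254 macrophage regions. On these chromosomes the lowest B cell height was 45.3, 11.7, 21.7 and 619, compared with 5.001 to 5.007 on the 15 chromosomes without a raised floor. In the macrophage list, chromosome 11 started at a height of 9.53 and held 3036 regions against 8061 in B cells, while the 15 chromosomes started between 6.001 and 6.386. The share of macrophage regions also found in B cells was 17.7% on chromosome 7 (interval 16.6 to 18.8), 34.2% on chromosome 14 (32.2 to 36.3) and 86.9% on chromosome 11 (85.6 to 88.0). Over the 15 chromosomes it ran from 64.6% on chromosome 15 to 79.7% on the X chromosome. The B cell share ran from 45.2% on chromosome 18 to 57.6% on the X chromosome. Library-only regions on chromosomes 7, 11, 12, 14 and 19 thus stood opposite a list with fewer low regions, and those chromosomes are left out of the site classes described next.

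**Figure D1:**
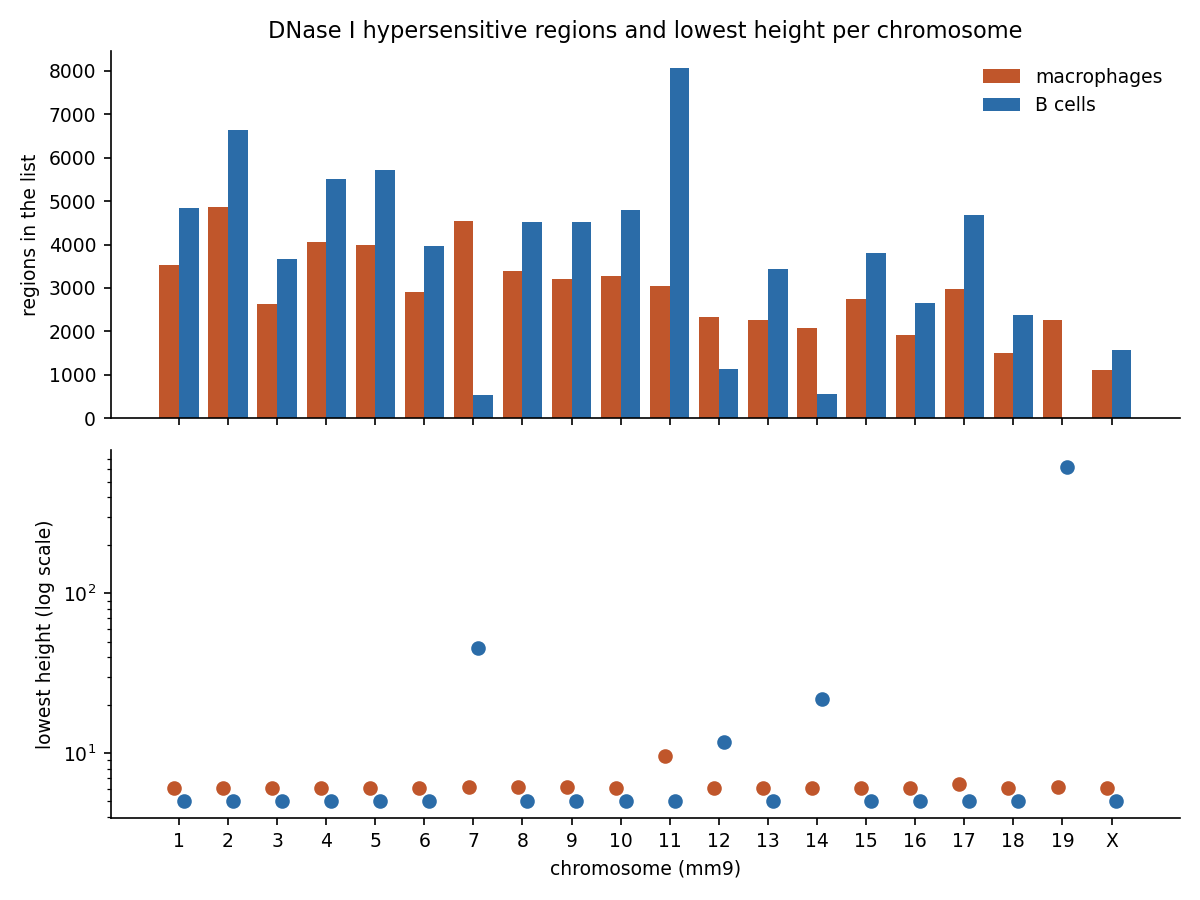
Number of regions per chromosome (upper panel) and the lowest height of any region on that chromosome, on a log scale (lower panel), for the macrophage and B cell lists (1 library each). The B cell list starts at heights of 45.3, 11.7, 21.7 and 619 on chromosomes 7, 12, 14 and 19, where its region numbers fall below those of macrophages.

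Shared sites were taller and wider than those of a single cell type. Among macrophage sites on the 15 chromosomes, 16569 were shared, with a median height of 12.6 (interquartile range 8.25 to 24.7) and a median width of 314 bp. The 9388 macrophage-only sites had a median height of 7.64 (6.68 to 9.56) and a width of 222 bp. Among B cell sites, 16440 were shared, with a median height of 18.7 (9.67 to 42.1) and a width of 370 bp, and 15506 were B cell-only, with a median height of 7.28 (5.90 to 10.6) and a width of 239 bp. Sites of several touching regions made up 47.6% of shared and 23.2% of macrophage-only sites, and 55.6% of shared and 37.9% of B cell-only sites. A wider site overlaps another by 1 bp more easily, so these contrasts in width and in touching regions are partly built into the classes. The classes were not compared at matched width. Sharing rose from 35.8% (interval 34.0 to 37.7) in the lowest of 10 equal groups of macrophage sites by height to 99.5% (99.1 to 99.7) in the highest group. In B cells it rose from 19.7% (18.3 to 21.1) to 95.9% (95.2 to 96.6). Of the library-only sites, 1171 in macrophages (12.5%) and 4343 in B cells (28.0%) were at least 2 times as high as the floor of their list. Most library-only sites thus lay within 2 times the floor, and weaker cutting at the same places in the other library could not be measured from these lists.

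**Figure D2:**
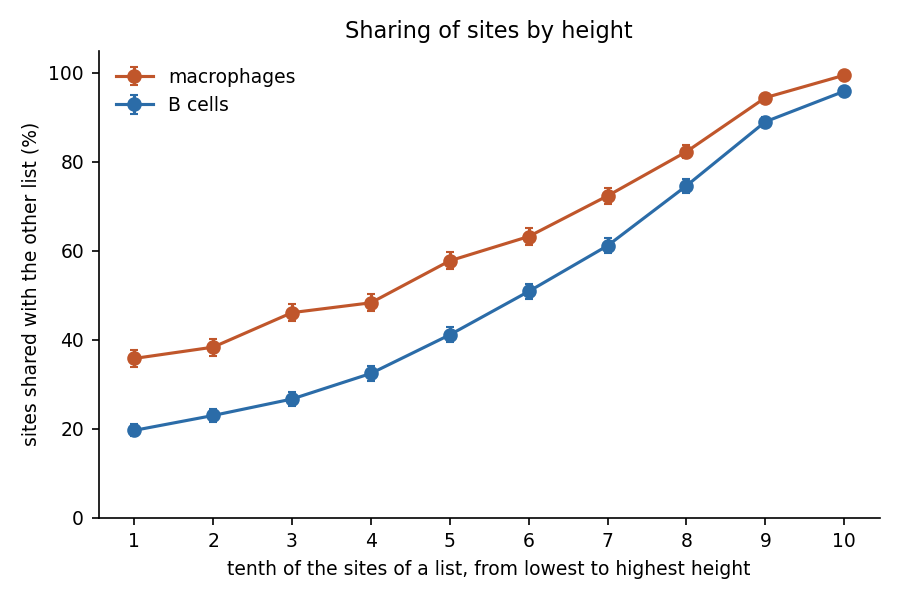
Share of merged sites that overlap a site of the other list, in percent, in 10 equal groups by height within each list, on the 15 chromosomes without a raised floor; bars are exact 95% intervals. The share climbs from 35.8% to 99.5% in macrophages and from 19.7% to 95.9% in B cells.

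The highest regions of each class were named by position. The 5 highest shared regions of macrophages and the 4 highest of B cells lay on chromosome 2 near 98.5 Mb, where the maximum at position 98507295 reached a height of 12508 in macrophages and 12001 in B cells. The fifth B cell region lay on the X chromosome from 139917482 to 139917647, with a height of 2057. Heights above 500 were also found in both lists near 40.0 Mb of chromosome 17, 61.3 Mb of chromosome 19 and 139.9 Mb of the X chromosome. The 99th percentile of height was 69.4 in macrophages and 118 in B cells. No region higher than 500 was checked against a control library or the genome sequence. Such heights are therefore given as deposited and are no evidence of strong hypersensitivity, also for the B cell-only regions named below. The 5 highest macrophage-only regions of the whole list were all on chromosome 19, where the B cell list held 1 region. On the 15 chromosomes the highest macrophage-only region lay on chromosome 8 from 129041175 to 129041361, with a height of 53.5. It was followed by chromosome 3 from 79371687 to 79372049 (49.2, part of a merged site of 3 regions that was shared), chromosome 2 from 131030306 to 131030626 (44.9), chromosome 6 from 125263762 to 125264203 (42.1) and chromosome 2 from 160192609 to 160193137 (41.2). Of the B cell-only regions on these chromosomes, the highest was a region of height 928 from 98506598 to 98506683 on chromosome 2, inside the group near 98.5 Mb and part of a merged site of 4 regions, from 98506598 to 98507167, that was shared. It was followed by chromosome 5 from 122670243 to 122670639 (218), chromosome 8 from 108147008 to 108147289 (170), chromosome 3 from 52247842 to 52248170 (164) and chromosome 5 from 121144043 to 121144409 (148). Over all chromosomes, a region on chromosome 14 from 46432489 to 46432644 (555) also ranked among the 5 highest B cell-only regions.

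The second comparison concerned the Pu.1 locus, whose promoter and upstream elements were the object of the study. Because no mm9 annotation was used, the interval described here was picked by the spacing of the published elements, and its identity as the Pu.1 locus was not checked against an annotation. Of 2948 placements tried on chromosome 2, 1 matched 6 of the 7 distances within 500 bp, and 3 matched 1 fewer. With a tolerance of 1000 bp, 9 placements tied at 6 matches, and with 300 bp the most matches fell to 5, reached by 2 placements. The unique placement put the promoter at position 90936847, reading toward higher coordinates. The spacing was matched without regard to cell type, but only sites holding regions of both lists were tried as the promoter. The presence of a site at the promoter in both lists was thus fixed by the search, and the presence of regions at the published distances was selected for, in whichever list.

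In this interval macrophages and B cells shared a site near -14 kb, macrophages alone had sites near -12 and -10 kb, and B cells alone had sites near -18 kb. The site placed as the promoter, shared by the construction of the search, ran from 90936641 to 90937769 in B cells, with 7 touching regions and a height of 34.2, and from 90936644 to 90937327 in macrophages, with 3 regions and a height of 17.6. These heights were above 87.6% of the B cell regions and 78.2% of the macrophage regions. The site near -14 kb, the published distance of the upstream regulatory element of Pu.1, had its maximum 13.6 kb upstream in both lists. It spanned 1472 bp in macrophages, from 90922849 to 90924321 (height 30.0), and 379 bp in B cells, from 90923078 to 90923457 (height 29.0). These heights exceeded 90.4% of macrophage regions and 85.0% of B cell regions.

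The macrophage-only site near -12 kb consisted of 5 touching regions from 90924374 to 90925141, with its maximum of 20.3 lying 12.1 kb upstream, above 82.3% of macrophage regions. A smaller macrophage-only site at -10.3 kb ran from 90926357 to 90926744 (height 11.1). The B cell list held no region within 500 bp of either distance, at a floor of 5.001 on this chromosome. At -9 kb, regions with heights of 8.69 in macrophages and 5.27 in B cells overlapped, but were no longer shared under a reciprocal overlap of 50% or with lists of equal length, which held no B cell region there. At -15 kb, macrophages alone had 2 regions, of heights 6.30 and 6.50, close to their floor of 6.001, and neither was among the top 50% by height. No region lay within 500 bp of -8 kb in either list. The B cell-only site at -18.1 kb ran from 90918629 to 90918960 with a height of 17.6, above 74.5% of the B cell regions, and a weaker site of height 5.42 followed at -17.8 kb. Downstream of the placement, macrophages alone had sites at 1.2 and 1.6 kb, with heights of 9.19 and 13.2. Farther upstream, outside the published distances, both lists held regions at -26.1 kb with heights of 102 in macrophages and 92.8 in B cells, above 99.8% and 97.8% of their lists, and at -42.7 kb in macrophages (43.7) and -42.5 kb in B cells (53.1).

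Between 20 kb upstream and 2 kb downstream, 24 regions were found in macrophages only and 4 in B cells only, while 9 macrophage and 8 B cell regions were shared. With touching regions merged, these were 7 macrophage-only and 2 B cell-only sites, and 5 macrophage and 3 B cell sites were shared. The macrophage list held 24 regions in a stretch of 6251 bp from 90921812 to 90928063, 19 of them macrophage-only, of which 7 were parts of the shared site near -14 kb, against 2 regions in the B cell list; this stretch was singled out after its values were seen. Of 13797 windows of the same length that started at another macrophage-only region outside this stretch, 3 held as many macrophage-only regions, and the median window held 1. The search had selected for regions at the published distances, and touching regions were counted singly, so these counts are no measure of rarity. With 1 library per cell type, the presence or absence of a region had no replicate check, and a region missing from a list may still have had reads below its floor.

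**Figure D3:**
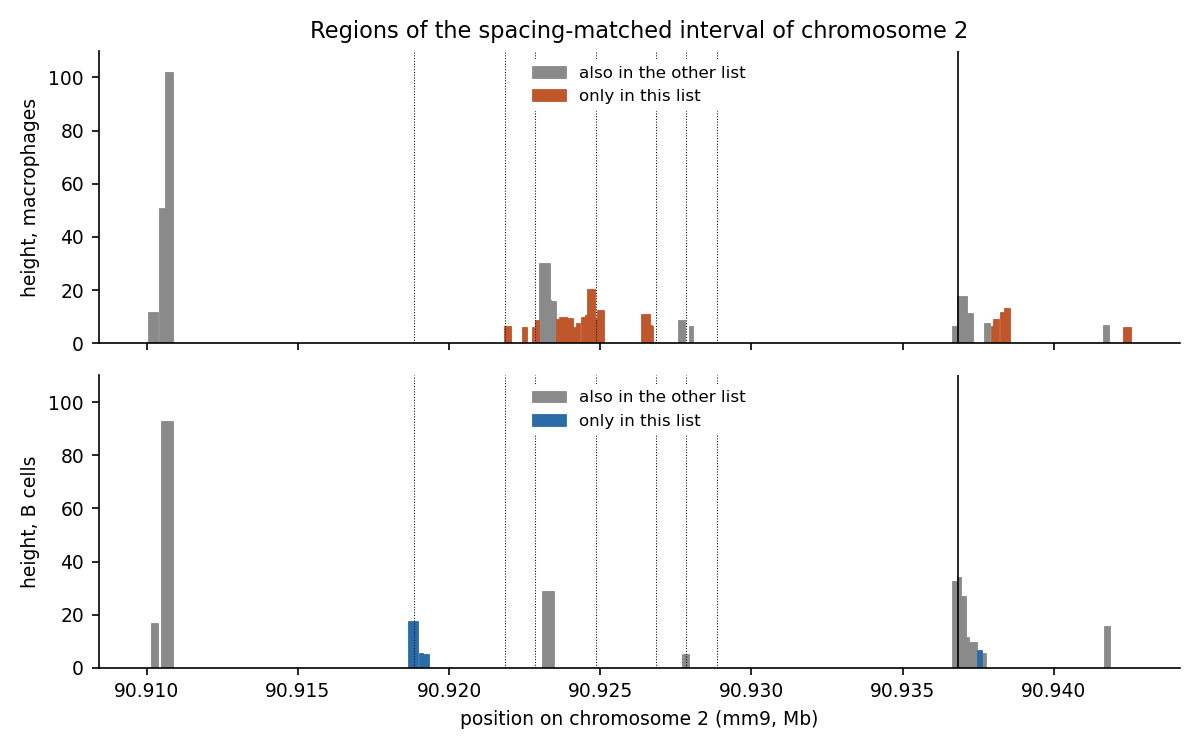
Height of each deposited region against its position on chromosome 2 (mm9) in macrophages (upper panel) and B cells (lower panel), 1 library each; coloured bars are regions of that list only, grey bars regions shared by overlap. The solid line marks the promoter placement at 90936847 and dotted lines the published distances from -18 to -8 kb: macrophages alone have bars at -12 and -10 kb, and B cells alone at -18 kb.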

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

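Alternatives called added, and the spacing search with all 3 of its tolerances, were chosen after seeing the data. The share of shared regions moved beyond its 95% interval in most settings, and the macrophage share stayed above the B cell share in 9 of 10. The exception was to count regions within 500 bp as shared, which gave 68.5% of macrophage and 69.6% of B cell regions. The B cell list was the longer one except with equal list lengths and with the 10000 highest regions. A longer list tends to have the lower share, so the count of 9 of 10 is no evidence of a difference between the cell types. A reciprocal overlap of 50% gave 37.4% and 30.1%; the top 50% by height 70.9% and 56.6%; equal list lengths 58.9% and 56.6%; and the 10000 highest regions 73.4% and 70.9%. Fixed widths of 200 bp gave 52.7% for B cells. Among the added settings, a common floor on each chromosome, which sets the same height in both lists though they were not known to share a scale, gave 66.9% and 57.8%, merged sites 57.2% and 51.7%, and the 15 chromosomes 68.9% for macrophages. Merging reduced the region counts to 34154 and 37398 by construction. In the chromosome 2 interval, from 50 kb upstream to 10 kb downstream, 25 macrophage-only, 7 B cell-only, 16 shared macrophage and 13 shared B cell regions were counted. The top 50% by height left 8 macrophage-only, 5 B cell-only, 10 shared macrophage and 8 shared B cell regions, so the macrophage-only excess was much smaller there. The site near -12 kb then still held 4 macrophage-only regions and the site near -18 kb 1 B cell-only region, while no region was left at -15 or -9 kb. The cause of these shifts was not tested beyond the shorter lists or the stricter overlap themselves. A reciprocal overlap of 50% gave 14 B cell-only, 6 shared macrophage and 6 shared B cell regions, and equal list lengths left 4 B cell-only regions. In the spacing search, 1 placement on chromosome 2 matched 6 distances at 500 bp and 9 did at 1000 bp, while at 300 bp the most matched were 5, by 2 placements. Values in the other settings stayed within their interval or within 1.5 times the count. The alternatives planned for the location of sites, the gene lists and the motif shares were not run, because no mm9 genome or annotation was used. The unknown read depth limits every statement on a missing region. No paired analysis was possible because each cell type had 1 library.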

Other observations

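The comparison of the highest region numbers and both tests on the chromosome 2 interval were chosen only after the results were seen, and the other tests were set on patterns already noticed in the data. The 100 kb windows were chosen after seeing the data.

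Sites found in 1 cell type were gathered in places, as counts of merged sites in windows of 100 kb on the 15 chromosomes without a raised floor showed. B cells had 192 windows with at least 10 B cell-only sites, which held 17.1% of all B cell-only sites, and macrophages had 56 such windows with 7.90% of the macrophage-only sites. There were 15506 B cell-only against 9388 macrophage-only sites, and no chance count was calculated for windows. The numbers of windows thus do not show that 1 class was more gathered than the other. The window richest in B cell-only sites, on chromosome 17 from 34.4 to 34.5 Mb, held 53 of them and 0 macrophage-only sites, and 17 of the 53 were at least 2 times as high as the floor, up to a height of 109. Chromosome 5 from 121.1 to 121.2 Mb held 33 B cell-only sites against 1, with no shared site, and 21 of them reached 2 floors. Chromosome 9 from 44.3 to 44.4 Mb held 30 against 3, and chromosome 18 from 60.9 to 61.0 Mb held 29 against 4. The window richest in macrophage-only sites, on chromosome 1 from 90.1 to 90.2 Mb, held 45 against 11, but 0 of the 45 reached 2 floors. Chromosome 10 from 127.0 to 127.1 Mb held 22 macrophage-only sites against 1, of which 6 reached 2 floors, and the X chromosome from 47.9 to 48.0 Mb held 19 against 0 with no shared site.

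The nearest library-only neighbour of a library-only site was of the same cell type for 73.5% of 24894 sites, against 53.1% ± 0.4 (SD) and at most 54.6% in 100 shuffles of the cell type within chromosomes. Splitting of 1 broad site into several regions does not account for all of it, since with neighbours closer than 5 kb left out the share was still 64.6%, above the highest shuffle of 54.2%. Weak regions lifted over the floor in 1 library do not account for all of it either. Among sites at least 2 floors high, the share at 5 kb or more was 74.4%, against 66.6% ± 0.7 and at most 68.4% in shuffles. A regional background strong enough to lift sites past 2 floors cannot be excluded by this cut. A difference between the libraries in regional base composition or copy number remains open, because no genome sequence was used and each cell type had 1 library, and no biological explanation was tested.

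The few B cell regions on chromosomes 7, 12, 14 and 19 may come from a height floor set separately on each chromosome. On 3 of the 3 such chromosomes with at least 100 B cell regions, the number of B cell regions at or above the raised floor, per macrophage region, lay within the range of the other 15 chromosomes; it was 0.116 on chromosome 7 (range 0.0595 to 0.122), 0.265 on chromosome 14 (0.244 to 0.316) and 0.487 on chromosome 12, only just above the lowest of 0.486 (highest 0.609, median 0.526). A large loss of reads on these chromosomes is argued against by the numbering of the regions. This holds only if the numbers count regions before filtering, which the file headers do not state. The numbering cannot speak to fewer open sites, since most numbers would then belong to regions that were not kept. On chromosome 7 the highest number among the listed B cell regions was 140899, against 528 regions. The highest region number on chromosome 7 in B cells was 0.661 times that in macrophages, against 0.665 to 0.716 on the other 14 autosomes without a raised floor, just below them, a gap far smaller than that between 528 and 4544 regions. The ratios of 0.677, 0.684 and 0.683 on chromosomes 12, 14 and 19 lay within that range. Which step of the processing raised the floor is not given in the sources used here, and the ratio above the floor was not assessed on chromosome 19, which held 1 B cell region. On the X chromosome the ratio of highest region numbers was 0.446.

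That the chromosome 2 interval is the Pu.1 locus is a hypothesis, which could be settled by an mm9 annotation. At 500 bp, 1 placement on chromosome 2 matched 6 of the 7 published distances, but the interval had been inspected and this tolerance chosen after seeing the data, and 9 placements tied at 1000 bp, so this match is no independent support. Chance spacing in a dense group of sites cannot be told apart from it by the search alone, since placements elsewhere matched as many distances in 91 of 29784 cases, a rate at which 9.01 would be expected on chromosome 2.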
